A study of Mus musculus with 2 samples.

How the data were processed

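Total RNA from hearts of mouse embryos (strain B6NCrl, embryonic day 10.5) was measured in 2 libraries of 1 group. Per the labels, each library came from a separate pool of embryos of both sexes (69 embryos in replicate 1 and 51 in replicate 2), used 10 ng of RNA above 200 nt, and held ERCC spike-ins. The labels link a manual for a SMARTer Ultra Low kit; whether ribosomal RNA was removed is not given in the sources used here. For each library the authors deposited a table per gene and a table per transcript. The deposited tables give an expected count and a posterior mean count (estimated counts of reads per feature, not normalised), TPM (a length-scaled relative abundance over all features, spike-ins included), FPKM, lengths, and lower and upper bounds of a credibility interval of TPM, which are treated as a score. The deposited transcript tables also give the percent of a gene's TPM that each transcript holds. The interval bounds belong to the posterior mean and need not contain the TPM itself. Per the labels and the deposited description, the assembly was mm10 and the annotation release M4. The quantifying program, its version and whether strand was used in counting are not given in the sources used here, so reads in overlapping genes are uncertain. A count shared between near-identical genes is an estimate, because such tables divide a read among the features it matches.

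Gene names, types and positions were taken from GENCODE release M21 (GRCm38, which is mm10). Of 43346 Ensembl genes in the tables, 42462 were matched and 884 were kept without a name. The tables held 69691 features in all, among them 26248 numbered short features and 96 ERCC spike-ins, which were left out of gene counts. Genes Ahsp and Snhg1, members of preset lists, were not found in the tables. Totals were 45205713 and 41070978 expected counts, of which 43295923 and 39786163 lay on mouse genes. At this depth a count of 0 allows up to 3 counts per library. Intervals and this floor cover counting error only, since reads without molecular identifiers are not independent molecules.

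The lists of genes, the pairs of genes, the genes whose isoforms were compared and all alternatives were fixed before the data were examined, except for 8 added lists and spike-in scaling of the count of differing genes. Detection was counted at 1 TPM in both libraries. Agreement was measured as Pearson's and Spearman's correlation across genes of log2(TPM + 1). Spread was estimated by edgeR 4.0.16 (with limma 3.58.1, R 4.3.3) as the common biological coefficient of variation after TMM scaling, on rounded expected counts. No p-value was computed, because 1 group of 2 libraries leaves no comparison of conditions. Differences between the libraries are log2 ratios of TMM-scaled counts, replicate 2 over replicate 1, with a prior count of 0.5. The median of each list with at least 4 genes of mean count 10 or more was compared with the central 95% of 10000 random lists matched in size and abundance over 20 bins. A gene was counted as differing where its mean count was 50 or more, its ratio at least 2-fold, and the deposited intervals of TPM did not overlap. A pair was called larger than the spread between libraries where both libraries gave the same sign and the mean log2 TPM ratio passed a limit built from the 500 genes nearest in mean TPM to each member (95th percentile of the absolute log2 ratios, combined as a root of summed squares). List shares are percentages of the TPM of nuclear protein-coding genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for the rest, and DESeq2 1.42.0 for alternative size factors.

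Named genes followed a rule: the 20 nuclear protein-coding genes with the highest mean TPM, the 4 most abundant members of each list and up to 4 of its members below 1 TPM in both libraries, both genes of each pair, the 10 differing genes with the largest ratio in each direction, the 10 most abundant noncoding genes, and the 2 main transcripts of each isoform gene. Other genes are said to have been chosen after their values were seen. The alternatives covered thresholds, pseudocounts, count minimums, DESeq2 size factors, deposited TPM, spike-in scaling, FPKM, posterior means, a correction for length and GC content, and each library alone. The procedure was tested on simulated data, with exact Poisson intervals of the counts in place of the deposited intervals of TPM. Of 200 genes with planted changes, 40.0% of the 2-fold and 100.0% of the 4-fold changes were counted as differing. Of the unchanged genes 4 were counted, and 11 of 200 unchanged lists, made of genes drawn at random, lay outside the central 95%. These simulations used a coefficient of variation of 0.1, below the 0.259 estimated for the 2 libraries; at 0.259 and with no planted change, a test added after the data were seen, 948 of 14084 genes were counted as differing. The coefficient of variation simulated at 0.1 was estimated at 0.0996 without planted changes and at 0.134 with them.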

Results

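The series measured RNA in the hearts of mouse embryos at embryonic day 10.5, a stage at which the looped heart beats while its chambers form. The embryos were of strain B6NCrl, a C57BL/6N substrain. There was 1 group with 2 biological replicates, a pool of hearts from 69 embryos (replicate 1) and a separate pool from 51 embryos (replicate 2), each of both sexes. Total RNA above 200 nt was sequenced from 10 ng per library, with ERCC spike-ins, synthetic RNAs added in set amounts. The libraries held 45205713 and 41070978 expected counts, of which 43295923 and 39786163 lay on mouse genes. No second condition was measured, so the comparisons below are between genes within this tissue and between the 2 pools. Every mean is given with its SD over n = 2 pools.

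Globin and heart muscle mRNAs were the most abundant protein-coding RNAs. Hbb-y, a beta globin of embryonic red cells (ENSMUSG00000052187.3, mm10 chromosome 7, 103851749 to 103853216), reached 16382.5 ± 3570.6 TPM, and the alpha globin Hba-a2 reached 9005 ± 1969 TPM. The cardiac alpha-actin Actc1 (ENSMUSG00000068614.7, chromosome 2, 114047282 to 114053548) stood at 8743 ± 3260.3 TPM and the atrial light chain Myl7 (chromosome 11, 5896637 to 5898782) at 6331 ± 772 TPM. Hbb-bh1 at 7874 ± 684 TPM and Hba-x at 7453 ± 496 TPM, the other embryonic globins, lay between them. Other genes among the 20 most abundant were the prolyl isomerase Ppia (4219 ± 105 TPM), the ferritin light chain Ftl1 (4003 ± 165 TPM), Ldha (3588 ± 183 TPM), Gapdh (3347 ± 399 TPM), the imprinted gene Mest (3245 ± 722 TPM) and Nppa (2899 ± 1270.3 TPM). Hba-a1 (4819.5 ± 1015 TPM) and Hba-a2 are near-identical copies, so the division of reads between them is uncertain.

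At 1 TPM or more in both pools, 13725 of 43346 genes were detected, among them 12172 of 21397 protein-coding genes, 632 of 5694 long noncoding RNAs and 558 of 7906 pseudogenes. Protein-coding genes held 81.9 ± 1.23% of all TPM, mitochondrial genes 2.37 ± 0.625%, pseudogenes 4.04 ± 0.22%, long noncoding RNAs 1.56 ± 0.202% and small structural RNAs 1.51 ± 0.232%. By expected counts the protein-coding share was 91.9 ± 0.765% and those of mitochondrial genes 1.17 ± 0.314%, pseudogenes 1.24 ± 0.0817% and small structural RNAs 0.134 ± 0.0279%, because TPM divides by length. Replication-dependent histone mRNAs, which lack poly(A) tails, were detected for 46 of 64 genes, with Hist1h2ap at 2573.5 ± 695.5 TPM, and histone copies share much sequence. Of the noncoding RNAs, the signal recognition particle RNAs Rn7s1 and Rn7s2 stood at 4633.5 ± 959 and 4633 ± 959 TPM, values that near-identical copies divide, and Malat1 at 3865 ± 108 TPM. H19 reached 548.5 ± 61.0 TPM and Meg3 351 ± 126 TPM. Malat1 had 48197 and 45230 counts against 29686 and 23189 for H19. Its lead over H19 was therefore smaller by counts, which are not divided by length. Gm26917 (2330.4 ± 675.5 TPM) and Gm42418 (2241 ± 1033 TPM) lie close together on the same strand of chromosome 17. They held 275829 and 156535 of the 789744 long noncoding counts in replicate 1, and 164137 and 71770 of 537953 in replicate 2. By counts, the long noncoding share thus rests in large part on these 2 genes. Whether their reads come from ribosomal RNA was not tested. Gm22133 (4210.3 ± 185 TPM) rested on 1321 and 1119 counts and lies within Ftl1 on the same strand, so its reads cannot be told from those of Ftl1. ERCC spike-ins held 7.9 ± 1.55% of all TPM and 3.68 ± 0.775% of counts.

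The 2 pools had similar rankings of genes. Pearson's r of log2(TPM + 1) was 0.971 and Spearman's rho 0.970 across 15191 genes, which are not independent replicates. The common biological coefficient of variation was 0.259 over 16536 genes. Among 47 spike-ins with a mean of 100 counts or more, the log2 ratios of the pools had an SD of 0.14, against 0.59 for 12092 protein-coding genes with the same minimum, and 0 of the spike-ins differed by 2-fold. The chi-square per degree of freedom over 17547 genes was 99.8, so the tables were not 1 library deposited under 2 names.

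**Figure D1:**
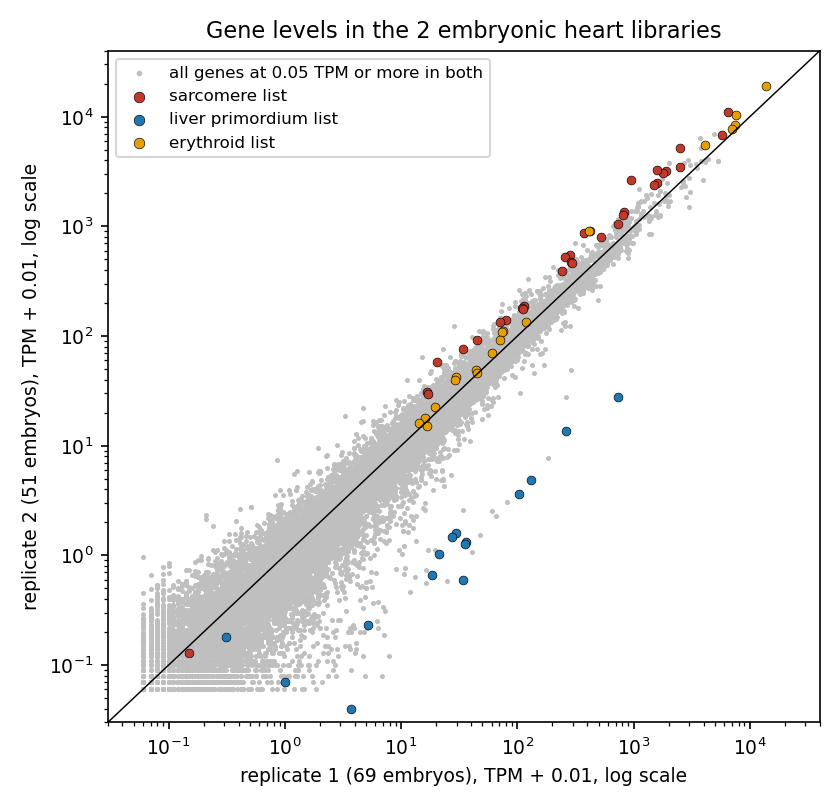
Each point is a gene, with TPM + 0.01 in replicate 1 on the horizontal and in replicate 2 on the vertical log axis, grey for genes at 0.05 TPM or more in both and coloured for members of 3 lists at any level. Liver genes lie below the line of equal values, for example Afp at 737 TPM in replicate 1 and 27.6 TPM in replicate 2, and most sarcomere and erythroid genes lie above it.

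Sarcomere genes, the contractile apparatus of heart muscle, made up 5.2 ± 1.75% of nuclear protein-coding TPM, and 31 of 33 were detected in both pools. Myom2 (0.13 ± 0.0141 TPM) and Xirp2 (0.015 ± 0.00707 TPM) were below 1 TPM in both. Actc1 exceeded the skeletal alpha-actin Acta1 by 12.3-fold and 13.8-fold in the pools (mean log2 ratio 3.70 ± 0.12), and cardiac troponin T, Tnnt2, exceeded Tnnt1 by 22.4-fold and 21.8-fold (4.46 ± 0.03). The slow skeletal troponin I, Tnni1 (2570 ± 940.3 TPM), was above the adult cardiac form Tnni3 (1042 ± 318 TPM) by a log2 ratio of 1.29 ± 0.09. Each of these passed the limit set by the spread between pools. The myosin heavy chains Myh7 (ENSMUSG00000053093.11, chromosome 14, 54970684 to 54994626) and Myh6 did not differ by more than that limit, at 1812 ± 1224 and 1088 ± 358.5 TPM (log2 ratio 0.59 ± 0.58). Nor did the atrial and ventricular regulatory light chains Myl7 and Myl2 (0.81 ± 0.56), though in replicate 1 alone (1.2) they passed their limit of 1.11, or the essential light chains Myl4 and Myl3 (-0.28 ± 0.25). The natriuretic peptide gene Nppa exceeded Nppb by a log2 ratio of 4.07 ± 0.29. The atrial list held 0.909% and 1.12% of nuclear protein-coding TPM in replicates 1 and 2 (1.02 ± 0.153%), the ventricular list 0.666% and 1.41% (1.04 ± 0.529%), so their order differed between the pools, and the trabecular list held 0.447 ± 0.201%. The atrial share rested mostly on Myl7 (6331 ± 772 TPM) and Myl4 (1930 ± 629 TPM). The median atrial gene stood at 28.4 TPM in replicate 1 and 16.4 TPM in replicate 2. The order of the atrial and ventricular shares therefore does not compare amounts of atrium and ventricle. By expected counts not divided by length the atrial share was 0.354%, the ventricular share 1.16% and the trabecular share 0.219%.

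**Figure D2:**
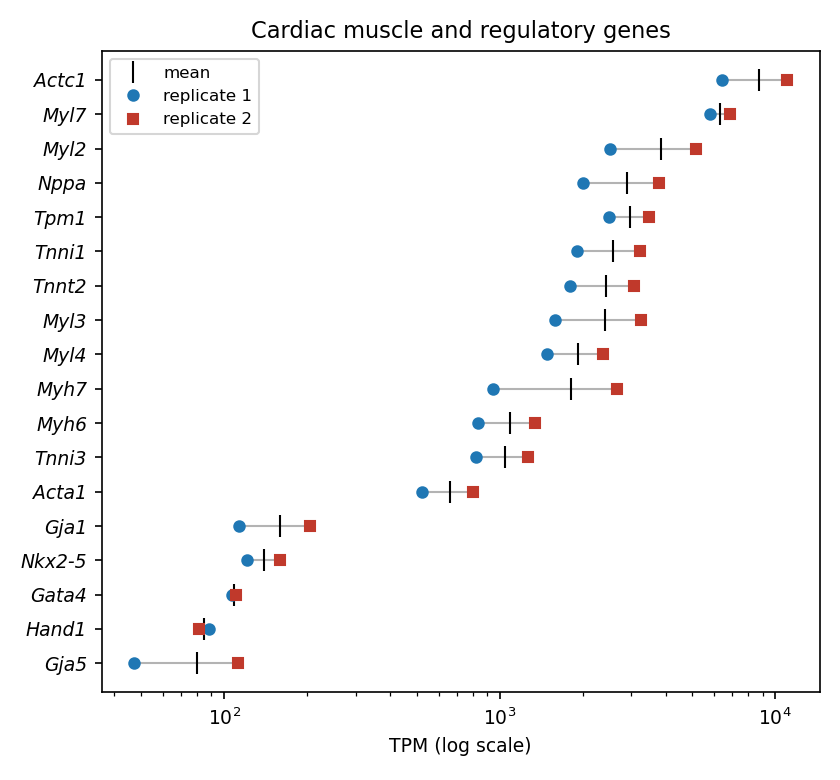
TPM on a log axis for 18 cardiac genes, with a circle for replicate 1, a square for replicate 2 and a bar at their mean. Actc1 is highest at a mean of 8743 TPM, and Myh7 shows the widest gap, from 946 TPM in replicate 1 to 2678 TPM in replicate 2.

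Among related enzymes of energy metabolism, the same gene was the higher in both pools. The glucose transporter Slc2a1 exceeded Slc2a4 by a log2 ratio of 4.92 ± 0.21, Ldha exceeded Ldhb by 3.07 ± 0.23, Eno1 exceeded Eno3 by 3.96 ± 0.42 and hexokinase Hk1 exceeded Hk2 by 2.29 ± 0.68. The brain-type creatine kinase Ckb (406 ± 103 TPM) was far above the muscle form Ckm (4.66 ± 2.85 TPM), at 6.57 ± 0.58. In contrast, the muscle form of carnitine palmitoyltransferase, Cpt1b (92.9 ± 44.2 TPM), was above the liver form Cpt1a (8.04 ± 3.06 TPM), with a log2 ratio of Cpt1a over Cpt1b of -3.5 ± 0.15. The broadly expressed cytochrome oxidase subunits exceeded the muscle forms, by 1.56 ± 0.26 for Cox7a2 over Cox7a1 and 1.72 ± 0.35 for Cox6a1 over Cox6a2. All of these passed the limit. Glycolysis genes held 2.29 ± 0.12% of nuclear protein-coding TPM and fatty acid oxidation genes 0.211 ± 0.0598%. The abundant mitochondrially encoded mRNA mt-Atp6 stood at 5979 ± 1466 TPM and mt-Nd1 at 2443 ± 968 TPM. The level of mt-Atp6 is the less certain, with deposited intervals of 3283.7 to 4818.4 TPM in replicate 1 and 4827.9 to 6977.7 TPM in replicate 2. Those of mt-Nd1 were narrow (1709.2 to 1741.1 and 3040.5 to 3084.8 TPM).

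Red cell genes held 5.7 ± 0.917% of nuclear protein-coding TPM. Hbb-y exceeded the adult beta globin Hbb-bs by a log2 ratio of 7.47 ± 0.07, a difference beyond the spread between pools. Hbb-bh1 over Hbb-y (-1.04 ± 0.19) and Hba-x over Hba-a1 (0.64 ± 0.21) stayed within it. By expected counts not divided by length, both passed the limit (-1.17 and 1.22), as did Hbb-bh1 over Hbb-y in replicate 2 alone (-1.18), and the red cell share was 1.92%. Hba-a1 shares reads with Hba-a2.

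Cardiac regulators were at lower levels. Nkx2-5, a homeobox factor of heart progenitors and myocytes, stood at 140.1 ± 27.4 TPM, the histone methyltransferase Smyd1 at 109 ± 54.0, Gata4 at 108.5 ± 2.53 and Hand1 at 84.3 ± 5.03 TPM, and all 31 cardiac transcription factors were detected in both pools. Gata4 exceeded Gata6 by a log2 ratio of 1.64 ± 0.33, and the log2 ratio of Hand2 over Hand1 was -2.87 ± 0.39. Among conduction genes, Gja1 exceeded Gja5 by 1.07 ± 0.27, which passed the limit of 1.04 with both pools but not in replicate 2 alone (0.88). The L-type calcium channel ratio of Cacna1d over Cacna1c was -3.56 ± 0.08. Cacna1d had 600 and 927 counts against 1971 and 3477 for Cacna1c, so the gap was smaller by counts not divided by length. The ligand ratio of Bmp10 over Bmp2 was -1.88 ± 0.44 and missed its limit of 1.63 in replicate 2 alone (-1.57). The pacemaker channel Hcn4 (2.83 ± 0.488 TPM) was above Hcn2, which had 1 and 2 counts, and this call was lost with a pseudocount of 1. Ryr2 over Itpr2 (-0.66 ± 0.25) stayed within the spread, but by expected counts passed the limit in the opposite direction (1.91). In all, 19 of 25 preset pairs passed the limit by TPM and 22 by expected counts.

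Most genes listed for other cell types of the heart were detected in both pools. Whether their transcripts came from the heart or from neighbouring tissue, whose markers were also present, was not tested. Endothelial genes, all 20 detected, held 0.12 ± 0.0149% of nuclear protein-coding TPM, led by Ramp2 (155 ± 23.4 TPM), Plvap (154 ± 15.8 TPM) and Egfl7 (147 ± 11.2 TPM). Cushion mesenchyme genes held 0.141 ± 0.0373%, led by the collagen genes Col3a1 (316 ± 76.5 TPM) and Col1a1 (191 ± 95.2 TPM) and the proteoglycan Vcan (115 ± 35.6 TPM). Epicardial genes held 0.0457 ± 0.00159%, with Upk3b at 101 ± 3.95 TPM and Tcf21 at 58.7 ± 6.58 TPM. Smooth muscle genes, which early heart muscle also expresses, held 0.274 ± 0.0375%, with Acta2 at 1784 ± 230 TPM and Myh11 at 0.375 ± 0.262 TPM. Cell cycle genes held 0.35 ± 0.0286%, with Cdk1 at 366 ± 27.1 TPM and Ccnb1 at 253 ± 3.73 TPM. Ribosomal protein genes held 5.61 ± 0.509% and imprinted genes 1.09 ± 0.00124%. The imprinted sum includes the noncoding H19 and Meg3, which the protein-coding denominator leaves out. Its small SD does not mean steady genes, since 8 imprinted genes were higher in replicate 2 and 10 in replicate 1. By expected counts not divided by length, the shares were 0.366% for cushion mesenchyme, 0.537% for cell cycle and 2.02% for ribosomal protein genes.

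For 12 genes the share of each transcript was compared. Pkm, whose M1 and M2 enzyme forms differ by a choice between adjacent exons, had the widest gap between pools among the main transcripts of these genes. Transcript Pkm-201, with exon 9 at chromosome 9, 59675568 to 59675734 (the downstream, M2-type exon), held 72.8% of Pkm TPM in replicate 1 and 52.1% in replicate 2 (62.5 ± 14.6%). Transcript Pkm-202, with exon 9 at 59675029 to 59675195 (the upstream, M1-type exon), held 27.2% and 47.9% (37.5 ± 14.6%). Total Pkm differed little, with a log2 ratio of 0.06 between pools. Tpm1-205 held 83.3% and 91.7% of Tpm1 TPM and Tpm1-213 held 7.75% and 2.09%. Tpm2-203 held 40.5% and 23.6%, and Tpm2-202 held 33.2% and 47.1%. Tnnt2-207 (60.6 ± 1.39%), Mef2a-208 (66.3 ± 0.987%), Camk2d-202 (43.1% in each pool) and Fn1-201 (48.2 ± 3.24%) led their genes in both pools. Myl6-201 is the single transcript listed for Myl6. Ttn-215, a short model of 2159 nt, led Ttn by TPM (66.0 ± 2.49%) but held 12.3% of its counts, and Ldb3-203 led Ldb3 by TPM (53.1 ± 0.547%) but held 25.9% of its counts. Mef2c-203 (62.8 ± 2.54% of TPM) and Actn1-202 (52.8 ± 1.97%) also led by TPM and not by counts (47.5% and 44.1%), and in replicate 1 the intervals of Actn1-202 and Actn1-201 overlapped. Transcript shares are estimates from reads that mostly fit several transcripts.

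**Figure D3:**
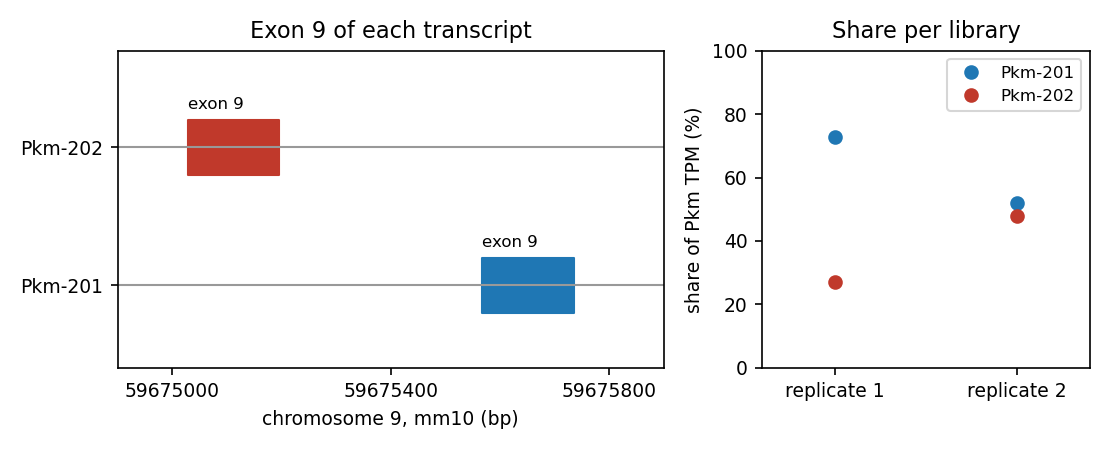
The left panel maps exon 9 of the transcripts Pkm-201 and Pkm-202 on mm10 chromosome 9 in base pairs, and the right panel plots the percent of Pkm TPM that each transcript held in each replicate. Pkm-201 holds 72.8% in replicate 1 and 52.1% in replicate 2, with Pkm-202 holding the rest.

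Transcripts of the liver primordium, which lies next to the embryonic heart, had the list median furthest from 0 between the pools. All 14 measured liver genes were higher in replicate 1, with a median log2 ratio (replicate 2 over replicate 1) of -4.65 and quartiles of -4.71 and -4.2, a median fold of 25.2. Matched random lists lay between -0.22 and 0.24. Afp, a serum protein of fetal liver and yolk sac (ENSMUSG00000054932.3, chromosome 5, 90490737 to 90508907), stood at 737 TPM in replicate 1 and 27.6 TPM in replicate 2, from 44527 and 1505 counts. Apoa2 stood at 262 and 13.8 TPM, Ambp at 132 and 4.9 TPM and Apoa1 at 103 and 3.66 TPM. Hnf4a, a liver and gut transcription factor, had 421 and 3 counts, a ratio of 119 (95% counting interval 40.5 to 579.6). The list held 0.178% of nuclear protein-coding TPM in replicate 1 and 0.00702% in replicate 2.

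Other lists of tissue around the heart were also higher in replicate 1. All 9 foregut and pharyngeal endoderm genes were higher there (median log2 ratio -2.11, with or without the floor for Nkx2-1), with Epcam at 22.8 and 4.96 TPM and Foxa2 at 3.38 and 0.3 TPM. All 14 measured Hox genes of paralog groups 1 to 5 were higher in replicate 1 (median -2.35), with Hoxb2 at 23.0 and 4.88 TPM. So were all 11 measured genes of groups 9 to 13, which mark trunk and limb levels (median -4.54, or -3.82 with 6 genes under 3 counts in a pool set to that floor). Hoxa9 stood at 4.71 and 0.32 TPM, and Hoxb9 had 46 and 0 counts. Skeletal myoblast genes were higher in replicate 1 for 5 of 5 (median -1.38), neural genes for 6 of 8 (-1.16) and neural crest genes for 7 of 11 (-0.98). The median skeletal myoblast gene stood at 0.38 and 0.14 TPM and the median neural gene at 0.46 and 0.21 TPM. The neural crest median turned to 0.15 at a minimum mean count of 100, and the neural median lay within its random range with deposited TPM (-0.73) and at that minimum (-0.86). At that minimum the foregut, skeletal myoblast and Hox 9 to 13 lists had too few genes for a value. Macrophage and platelet genes were higher in replicate 1 for 15 of 16 (-0.96), the exception being Lyz2 (1.33).

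Heart muscle genes were higher in replicate 2, the pool with the lower liver transcripts (median -4.65). Of 32 measured sarcomere genes, 31 were higher in replicate 2 and 12 of them by at least 2-fold (median log2 ratio 0.86, matched random lists between -0.07 and 0.22). Myh7 had the log2 ratio 1.59, Myl2 1.13, Actc1 0.87 and Myl7 0.34, while Myom2, with 19 and 16 counts, was at -0.01. Ventricular genes were higher for 7 of 8 (1.12), the exception being Hand1 (-0.03). All 6 trabecular genes were higher (1.13), among them Nppb (1.42), Gja5 (1.41), Cited1 (1.25) and Nppa (1.01). The atrial list lay within its random range (0.30), with Myl4 at 0.77 and Stard10 at -1.28. Calcium and ion channel genes were higher for 19 of 23 (0.64), with Pln, the inhibitor of the calcium pump, at 1.49 and Gja1 at 0.95. All 16 fatty acid oxidation genes were higher in replicate 2 (0.73), with Fabp3 at 1.16, and so were all 13 mitochondrially encoded mRNAs (0.59), with mt-Nd1 at 0.92. The atrial list aside, these lists were also outside their random ranges with deposited TPM.

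**Figure D4:**
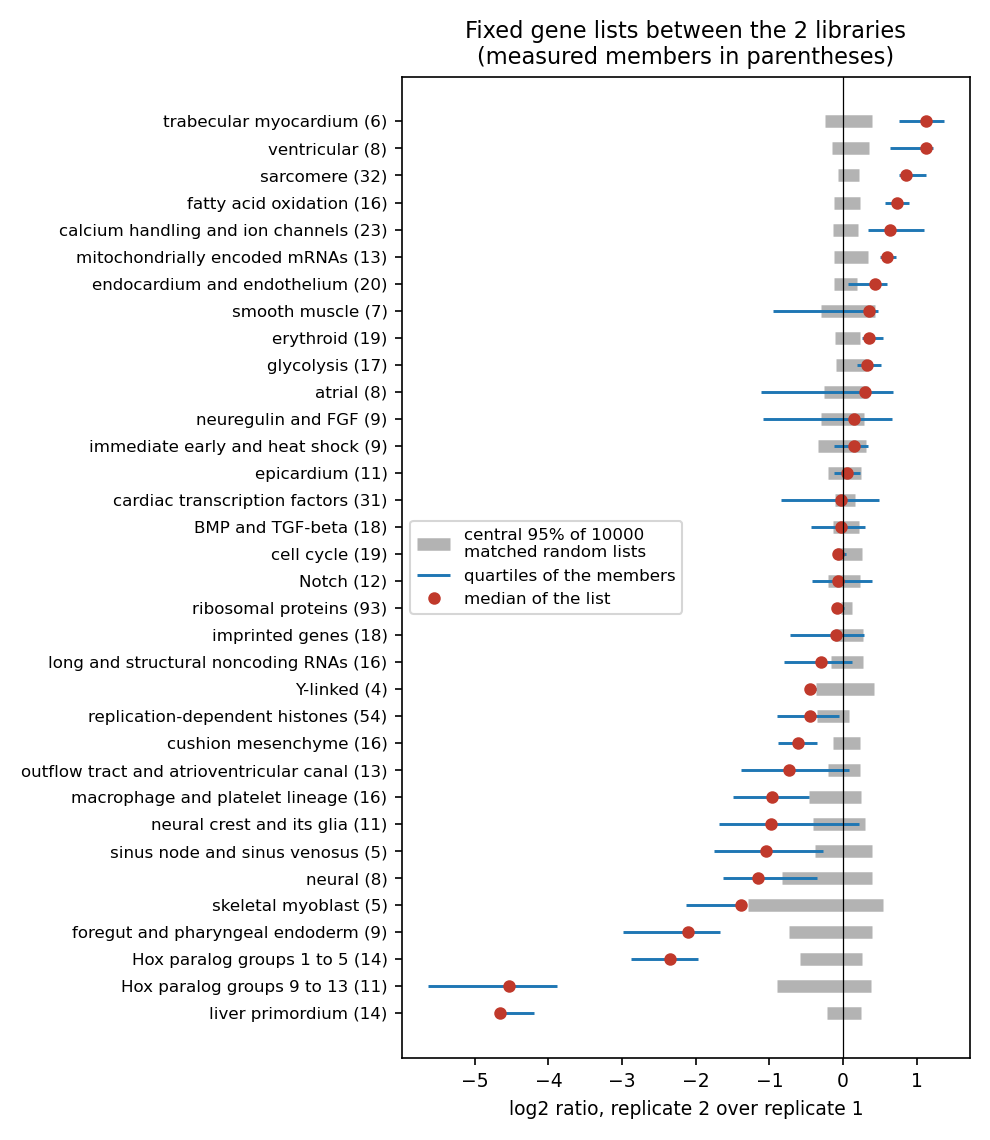
Median log2 ratio of replicate 2 over replicate 1 for the 34 fixed lists (red points), with member quartiles (blue lines) and the central 95% of 10000 matched random lists (grey bars). Medians run from -4.65 for liver genes to 1.13 for trabecular genes, and medians between -0.33 and 0 change sign under spike-in scaling.

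Red cell genes were higher in replicate 2 for 18 of 19 (median 0.35), with Hbb-y at 0.54 and Hba-x at 0.21. Endothelial genes were higher for 15 of 20 (0.44), with Eng at 0.89 and Egfl7 at -0.06. Glycolysis genes were higher for 16 of 17 (0.33), though with deposited TPM their median (0.19) lay within the random range. Cushion mesenchyme genes were higher in replicate 1 for 14 of 16 (-0.61), with Col1a1 at -0.97 and Vcan at 0.6. Outflow tract and atrioventricular canal genes were higher in replicate 1 for 8 of 13 (-0.73) and sinus venosus genes for 5 of 5 (-1.05). Of the latter, the pacemaker factor Shox2 (-2.71) and Isl1 (-1.75) differed most, while Tbx18 (-0.03) and Hcn4 (-0.26) differed little. Of the outflow and sinus lists, 7 of 13 and 5 of 5 genes are also in other lists. Markers of other tissues (liver -4.65, Hox groups 1 to 5 -2.35) were higher in the same pool. Histone genes were higher in replicate 1 for 42 of 54 (-0.44, or -0.45 with 1 gene set to the floor) and the 4 Y-linked genes for 4 of 4 (-0.44). Ribosomal protein genes (66 of 93 higher in replicate 1, -0.08) and noncoding RNAs (11 of 16, -0.3) had the opposite sign under spike-in scaling (0.26 and 0.03), which adds one offset to every ratio, and the noncoding median lay within its random range after a correction for length and GC content (-0.15). The medians of the cardiac transcription factors (-0.03), epicardium (0.06), smooth muscle (0.35), cell cycle (-0.07), Notch (-0.07), BMP and TGF-beta (-0.03), neuregulin and FGF (0.15), imprinted (-0.1) and immediate early (0.15) lists lay within their random ranges, and those of them below 0 turn positive under spike-in scaling. In all, 24 of 34 fixed lists were outside. Random lists were drawn gene by gene, whereas genes of 1 tissue or pathway can move together, and several lists share genes. The 24 are therefore not independent results, and a single difference between the pools could place many of them outside.

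Of 14131 genes with enough counts, 1002 (7.09%) were counted as differing between the pools, 683 higher in replicate 1 and 319 higher in replicate 2. Libraries were also simulated without any change but with the observed coefficient of variation of 0.259, which itself includes the differences between the pools. In them 948 of 14084 genes (6.73%) were counted, by Poisson intervals of counts and not by the deposited intervals. The number alone therefore does not set the 2 real libraries apart from random spread of that size. The 1002 genes included 13 liver genes, all higher in replicate 1, and 12 sarcomere genes. Nepn, with 334 and 0 counts, was at least 94.5-fold higher in replicate 1. Rhbg had 381 and 4 counts, Serpina1d 310 and 4, Fgg 1659 and 26, and the glucagon gene Gcg 138 and 2 (ratio 58.5, interval 15.9 to 488). The lung and thyroid factor Nkx2-1 had 104 and 1 counts (ratio 88.2, interval 15.5 to 3518). On the other side, Gtsf1 (62 and 312 counts, log2 ratio 2.56), Lyz1 (2.4), Scin (2.36), Prr15 (2.3) and the sarcomere-associated genes Mypn (2.2) and Nrap (2.03) were higher in replicate 2. Spike-in scaling, chosen after the data were seen, gave 1298 differing genes, 437 higher in replicate 1 and 861 higher in replicate 2, with 756 shared, so the direction of the split depends on the scaling. TMM left the median of all genes at -0.02, deposited TPM moved it to -0.1 and spike-in scaling to 0.32, so that ratios between -0.33 and 0 change sign under the latter. These counts describe 2 libraries and not a condition, and pool differences in dissection, stage and handling cannot be separated with 1 library per pool.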

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

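The tests of yolk sac, dilution, ventricle and stage in this part were chosen after the result was seen. The design names 1 group, so no biological explanation between groups was tested, and stage, ventricle and sex were tested as differences between the pools. The numbered short features, which no comparison used, held 55 counts in replicate 1 and 43 in replicate 2, on 5 features in each library, more than a count of 0 allows. They are 61 to 259 nt long, and 99.76% of the 26248 features have an effective length of 0 in the tables. The phiX control held 0 and 0 counts.

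Markers of tissue around the heart were higher in replicate 1. The median of the 5 list medians (liver, foregut, skeletal myoblast, neural and neural crest) was -1.38, all 5 negative and outside their random ranges, which is consistent with more neighbouring tissue dissected with the hearts in that pool, although the neural crest median was 0.15 at a minimum mean count of 100, the neural median lay within its random range there (-0.86) and with deposited TPM (-0.73), and the skeletal myoblast median, from 5 of 9 genes, lay just past its range (-1.29). Most of the signal lay in the liver list (Afp 737 and 27.6 TPM, Apoa2 262 and 13.8 TPM), of which 9 of 15 members reached 1 TPM in both pools and 1 is in another list; for the foregut list this was 2 of 9 and 1. Yolk sac endoderm, which shares Afp and apolipoproteins with liver, cannot be told apart as a source: its own list had a median of 0.057 against -3.59 for hepatoblast genes, but its members went both ways and its median member stood at 4.26 and 1.76 TPM. Its most abundant members, Slc39a8 (40.95 and 40.4 TPM) and Rhox5 (12.6 and 12.0 TPM), differed little, 5 of its 8 members reached 1 TPM in both pools and 0 are in other lists.

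Heart muscle transcripts were higher in replicate 2, and the ventricular median exceeded the atrial median by 0.82 (random range -0.34 to 0.44), or by 1.05 without sarcomere genes (-0.39 to 0.57), with 7 of 8 ventricular and 5 of 8 atrial genes in other lists. More ventricle in that pool would give such a difference, but Stard10, Nr2f1 and Nr2f2, 3 of the 8 atrial genes, are also expressed outside the heart. They were at least 2-fold higher in replicate 1, so other tissue there may contribute. Leaving them out gave 0.48, within its random range (-0.52 to 0.5). This decides nothing, because they were picked after the result was seen and were the 3 atrial genes higher in replicate 1. Their removal therefore had to raise the atrial median. Plain dilution of heart RNA by other tissue in replicate 1 would move all heart lists alike, unless that tissue also expresses their genes, which was not tested. The medians were 0.86 for sarcomere, 0.44 for endothelial, 0.06 for epicardial and -0.61 for cushion genes. Dilution also predicts steady ratios among muscle genes. The root mean square change of 6 myofilament pairs, 0.49, lay within the range of random pairs (0.19 to 0.84). Random pairs came from the same 2 libraries and carry any difference between the pools, so lying within their range does not speak for dilution. The changes were 0.82 for Myh7 over Myh6, -0.79 for Myl7 over Myl2 and -0.36 for Myl4 over Myl3. They were 0.17 for Actc1 over Acta1, 0.13 for Tnni1 over Tnni3 and -0.04 for Tnnt2 over Tnnt1. Some pairs thus moved and others held steady, and dilution cannot be told apart from other causes with 2 libraries. The comparison for this test and the next was revised after a first result: against pairs of spike-ins, whose noise is technical alone, the change in these pairs was larger (0.49 against 0.21) and had been read as evidence against dilution alone. A later stage of the embryos in replicate 2 cannot be told apart either. The mean change toward later globins in 3 pairs, 0.22, lay within the random range of -0.49 to 0.43. Hbb-bh1 over Hbb-y changed by -0.271, Hba-x over Hba-a1 by -0.297 and Hbb-y over Hbb-bs by -0.101, each toward the later globin. Their mean change was just above the 95th percentile for pairs of spike-ins, 0.21, which holds technical noise alone.

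Y-linked genes were higher in replicate 1, and Xist, named by this test but outside the rule for named genes, was slightly higher in replicate 2. The Y-linked median was -0.44 and the ratio of Xist 0.34, opposite in sign as different shares of male and female embryos in the pools could give. Both lay under the 95th percentile of genes of like abundance (1.15 and 1.04), an outcome that the bound written before the result was seen would have read as evidence against that explanation. That bound was wrong for this design, because passing it would need a change of over 2-fold in the share of a sex between mixed pools. Against matched random lists, the Y-linked median lay outside the range (-0.36 to 0.42), while Xist is a single gene within its limit. Whether the shares of the sexes differed therefore cannot be told, because each pool holds both sexes and the pools number 2.

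Of the 19 measured red cell genes, 94.7% had 1 sign, higher in replicate 2, as different carry-over of blood in the pools predicts. Their median, 0.35, was close to those of glycolysis (0.33) and endothelial genes (0.44), so the shift was not particular to red cells. Macrophage and platelet genes were higher in replicate 1 (-0.96). Blood carry-over therefore cannot be told apart from other causes. Across genes the log2 ratio had a Spearman correlation of -0.0704 with GC content and 0.0499 with length. Both lay under the bound of 0.1 set for no trend, so a trend over all genes was an unlikely cause of the differences. Such a correlation cannot exclude an effect in some class of genes. The noncoding median lay within its random range after the correction for length and GC content.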

How the results depend on the processing

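The spike-in scaling of the count of differing genes was chosen after the data were seen; the other alternatives were planned. By expected counts in place of TPM, the protein-coding share of RNA was 91.9% and the red cell share 1.92%, since counts are not divided by length; with all deposited TPM as the denominator, which adds spike-ins and noncoding RNAs, the red cell share was 4.69%. The correlation of the pools was 0.941 with a pseudocount of 0.1, and the coefficient of variation 0.308 with no filter beyond 1 count; the cause was not tested. Under spike-in scaling the noncoding median turned to 0.034 and the ribosomal protein median to 0.26, as one offset added to every ratio gives. At a minimum mean count of 100 the neural crest median turned to 0.15 (fewer genes measured), and the skeletal myoblast, foregut and Hox 9 to 13 lists had too few genes for a value. A lower fold threshold gave 2320 differing genes and a minimum mean count of 200 gave 511, as a looser and a stricter filter do. Spike-in scaling gave 1298 and DESeq2 size factors 997, of which 756 and 989 were shared with TMM. Lists outside their random ranges numbered 24 of 34 with TMM (DESeq2 size factors and spike-in scaling, which add one offset to every ratio, cannot change this), 22 with deposited TPM, 26 with no minimum (the neuregulin and imprinted lists added), 23 after a correction for length and GC content (noncoding RNAs lost at -0.155) and 19 of 31 at the higher minimum. With 1 library alone, the detected genes ranged over 14167 to 14749, the sarcomere share over 3.96 to 6.43% and the red cell share over 5.05 to 6.34%; differences between the pools have no such value. Genes near 0 counts are limited by depth.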

Other observations

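All the lists and genes in this part and their tests were chosen after the data were seen. Gut mesenchyme genes were higher in replicate 1 for 5 of 5 (median log2 ratio -2.37, random lists -0.87 to 0.49), led by Foxf1 at 34.4 and 2.61 TPM and Barx1 at 9.74 and 2.19 TPM; 2 of 5 members reached 1 TPM in both pools. Limb bud genes were higher in replicate 1 for 10 of 10 (-2.14, or -2.15 with En1 set to 3 counts), led by Sall4 at 17.9 and 8.98 TPM and Fgf8 at 7.38 and 1.61 TPM; 3 of 10 reached 1 TPM in both and 2 are in other lists. Hepatoblast genes were higher for 10 of 12 (-3.59), led by the imprinted gene Dlk1 at 289 and 48.6 TPM and Serpinf2 at 81.5 and 3.07 TPM; 5 of 12 reached 1 TPM in both and 2 are in other lists. Nephric genes were higher for 5 of 7 (-1.86), led by Gata3 at 18.1 and 7.7 TPM and Osr1 at 11.6 and 1.62 TPM, and surface ectoderm genes for 6 of 7 (-1.59), the exception being its most abundant member, Perp, at 43.5 and 77.1 TPM (log2 ratio 0.91). Lung bud genes (4 of 6, -0.8) had the same direction, and the trophoblast list had too few genes for a value.

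A further 3 muscle genes not named above were each higher in replicate 2. Myoglobin, Mb, stood at 23.0 TPM in replicate 1 and 76.8 in replicate 2 (log2 ratio 1.83). The striated muscle cytochrome oxidase subunit Cox8b stood at 11.2 and 39.5 TPM (1.89). The calcium store protein Casq2, a member of the fixed calcium and ion channel list, stood at 4.66 and 16.8 TPM (1.93). These 3 genes were picked for their ratios and are examples, not a test.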
